A study of Mus musculus with 2 samples.

How the data were processed

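Single-cell RNA was measured in mouse vein grafts, veins implanted into the circulation of adult C57BL6/J mice. The labels give 2 samples, 1 of conventional grafts and 1 of No-Touch grafts, in which the vein is moved together with the tissue around it. Per the labels' protocols, grafts were digested with papain and then with collagenase and dispase, and live nucleated cells without surface CD45, the antigen of leukocytes, were sorted before droplet capture on the 10x Genomics platform. The labels do not settle which version of the 10x kit was used for each library, so the libraries may differ in it. The number of animals and grafts behind each library is not given in the sources used here. Groups were taken from the sample titles.

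The deposited values are UMI counts per gene and cell barcode, 1 filtered matrix per library. Per the submitters' processing notes the counts were made with Cell Ranger 3.1.0 on the mm10 genome, while per the file headers the matrices were written by Cell Ranger 6.0.0, and this difference could not be settled. The deposited counts hold 11899 barcodes and 200851272 UMIs in the conventional library and 12450 barcodes and 373319906 UMIs in the No-Touch library. Whether the strand was used in counting is not given in the sources used here, so counts of antisense genes are uncertain. MHC class I genes are close copies of each other, and how counts were split between them is uncertain too.

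Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept, which left 10458 and 11525. Doublets were called per library with Scrublet in scanpy 1.11.5. Its automatic threshold marked 2.30% of the conventional barcodes, and these 241 were removed. In the No-Touch library it marked 0%, so by the rule fixed for that case the 1063 highest scores (9.22%) were removed. The libraries were thus treated unequally, and an alternative with the same rule in both was added after seeing the data. The kept cells numbered 10217 and 10462.

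Counts were scaled to 10000 per cell and log transformed, 2000 variable genes were chosen within the libraries, and 30 principal components with 15 neighbours gave Leiden clusters at resolution 1.0, without batch integration. Clusters were named from markers fixed in advance. The scoring rule was set after the clusters were seen, because a first version gave names from very low counts. It required 3 markers detected in at least 10% of cells, set each marker against its highest cluster or 200 CPM, and left a cluster unnamed when the best scores of different classes lay within 0.05. Cluster 12, with mesothelial markers, stayed unnamed for that reason (205 conventional and 20 No-Touch cells); a smaller margin was tried and put back. A cluster also lost its name when its 10 leading genes by fold held more markers of another class than of its own. With the fold taken over all other cells, clusters 5, 7 and 20 of the 12 with fibroblast scores were set aside. With the fold over the median of the other clusters only cluster 20 failed, and over the median of the other classes 0 of the 12 failed. The first of these was kept as the strictest, after all were seen, and the class with these clusters put back is an added alternative. Subclusters were made from the classes before this step, at resolution 0.5.

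Within each class of at least 200 cells in both libraries, UMIs were summed per library and gene and scaled to the same total per library and class (CPM). Ratios are No-Touch over conventional of CPM + 1 on the log2 scale. Genes of at least 50 CPM in either library were counted when at least 2 times apart. For 30 gene lists fixed in advance, members of at least 10 CPM were counted when at least 1.5 times apart, and the median log2 ratio was placed among 10000 random lists of the same size matched on expression in 20 bins. That percentile describes these libraries and is not a p-value. The haemoglobin list had no member of 10 CPM in the 4 classes compared, so it has no median and no alternative values. Named genes are the 10 highest and 10 lowest ratios per class among genes of at least 100 CPM, leaving out mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, sex-linked and predicted genes, markers of other classes and genes under 10% of their highest class. From each list described, up to 4 members with the largest ratios and at least 20 CPM are named, with the 2 highest members added when the median lay within 0.2 of 0. Not every gene this rule gives is named in the text, and the figure of these genes shows 8 each way. Genes named outside this rule were chosen after their values were seen. Positions come from GENCODE vM21 on mm10, in which all 296 named genes had one.

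With 1 library per group no test was possible, so no p-value or standard error is given, and no difference has a replicate check. Intervals are exact at 95%, Garwood's for counts and Clopper-Pearson's for shares, and cover counting error only. Bounds on a ratio of shares set the interval ends against each other. The comparison step was checked on simulated counts drawn from the class sums with known folds. Both libraries were drawn from the same averaged profile with Poisson noise alone. The check therefore covers counting error and not differences between libraries or in cluster makeup. In fibroblasts (2910 genes), blood endothelial cells (3303), lymphatic endothelial cells (3418) and mural cells (3267), 100% of genes at 3 or 4 times were counted, and 0 unchanged genes. Of genes set at exactly 2 times, 51.2%, 39.6%, 30.4% and 53.8% were counted, so counts at that limit miss genes close to it.

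For shares of cycling cells each cell was thinned to 3000 UMIs, which left out 613 shallower conventional cells (6.00%) and 224 No-Touch cells (2.14%). The filters, doublet rule, markers, lists, thresholds, named-gene rule and all alternative settings but the 3 named below were fixed before the data were examined. Alternatives covered the filters, doublets, resolution, separate clustering, thinning, TMM scaling with edgeR 4.0.16 in R 4.3.3, median-of-ratios scaling, cell weighting, pseudocounts and expression minimums. Equal doublet removal, the clusters put back and cells of male type alone were added after seeing the data, and the lists whose counts lead each comparison were chosen then too. Other tools were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.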

Results

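The series holds 2 single-cell RNA libraries of cells sorted as CD45 negative from mouse vein grafts, 1 of conventional and 1 of No-Touch grafts. In kept cells the median depth was 16607 UMIs in the conventional and 27457.5 in the No-Touch library, a ratio of 1.65, with medians of 3970 and 5276.5 genes. Mitochondrial UMIs had a median of 2.33% and 1.70%. The sums over kept cells were 191111045 and 322902564 UMIs. Because each group is 1 library, all values below compare these libraries and not the graft types.

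The first comparison asks which cell types made up the grafts. Fibroblast-like cells, which make the matrix of the vessel's outer coat, were the most frequent class in both libraries. They made up 56.3% (55.3 to 57.2) of conventional and 44.8% (43.8 to 45.7) of No-Touch cells. Mural-like cells, the smooth muscle cells and pericytes of vessel walls, made up 11.0% (10.4 to 11.7) and 7.88% (7.37 to 8.41). Blood endothelial-like cells, which line blood vessels, made up 8.55% (8.02 to 9.11) and 3.65% (3.30 to 4.03), a ratio of 0.427. Lymphatic endothelial-like cells made up 3.22% and 2.77%, within counting error of each other. The direction for fibroblasts depends on clusters 5, 7 and 20, set aside by the check on leading genes, which held 8.57% of conventional and 32.3% of No-Touch cells. With them put back the shares were 64.8% and 77.0%, the reverse direction.

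Among smaller classes, Schwann-like cells of nerves made up 1.85% of conventional and 2.98% of No-Touch cells. Neutrophil-like cells made up 5.75% and 1.27%, and mononuclear phagocyte-like cells 0.763% and 1.88%. T or NK-like cells numbered 9 and 173, and B-like cells 10 and 26. Epithelial-like cells made up 1.80% and 0.430%, a difference that lay in cluster 22, led by Pth (145 and 7 cells), since cluster 21 held 39 and 38. The digestion, the sort and tissue carried along at surgery can all set these shares. Ptprc, which encodes CD45, lay between 0.801 and 2.76 CPM in the 4 classes compared below, with clusters 5, 7 and 20 counted as fibroblasts, against 604 and 985 CPM in neutrophils.

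**Figure D1:**
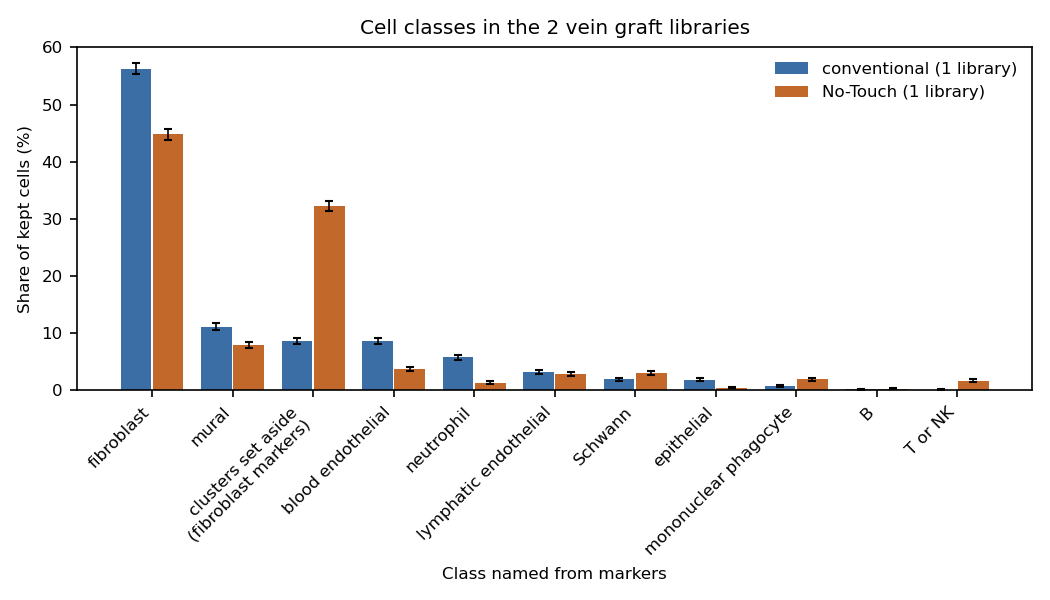
Bars give the share of kept cells (%) in each class for the conventional (blue) and No-Touch (orange) library, with exact 95% intervals that cover counting error only. Fibroblasts were at 56.3% and 44.8%, and the clusters set aside were at 8.57% and 32.3%.

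In fibroblasts, collagen and interferon response genes were higher in the No-Touch library, and some genes of inflammation and complement were lower over the whole class. Of 15 collagens, the fibrous proteins of connective tissue, 11 were at least 1.5 times higher and 0 lower, with a median log2 ratio of 0.91 (percentile 100). Col3a1 was at 8421 CPM (8406 to 8437) in the conventional and 17398 CPM (17378 to 17417) in the No-Touch library, and Col5a1 and Col6a3 had log2 ratios of 1.13 and 1.24. Of 16 genes of myofibroblast activation 8 were higher and 1 lower (median 0.62), among them the matrix genes Cthrc1 (172 and 612 CPM; chromosome 15, 39076932 to 39087121), Postn (717 and 1772 CPM) and Aspn (582 and 1326 CPM). Of 20 interferon response genes 10 were higher and 0 lower (median 0.56, percentile 100). These included Isg15, a ubiquitin-like protein induced by interferon (121 and 312 CPM), Xaf1 (31.0 and 75.2 CPM) and Rtp4 (51.8 and 118 CPM).

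Of 25 genes for cytokines, chemokines and targets of NF-kappaB, a transcription factor of inflammation, 11 were at least 1.5 times lower and 2 higher in No-Touch fibroblasts (median -0.44, percentile 0). The list of immediate early and heat shock genes, which digestion of tissue can induce, had a median of -0.33 in these cells, with 3 of 20 members lower and 1 higher, but was above 0 in 7 of 10 clusters (-0.43 to 0.42). Saa3, an acute phase protein, was at 3447 CPM (3437 to 3457) and 1062 CPM (1057 to 1066; chromosome 7, 46711998 to 46715700), and the B cell chemokine Cxcl13 at 121 and 12.5 CPM. Icam1, an adhesion molecule for leukocytes, was at 1550 and 394 CPM (chromosome 9, 21015985 to 21028817). Of 8 complement genes 3 were lower and 0 higher (median -0.53), with C3, the central complement protein, at 5876 and 2336 CPM. Among 17 genes of hypoxia and glycolysis 5 were lower and 0 higher (median -0.36), and among 17 growth factors 6 were lower and 1 higher (median -0.27). MHC genes, which present antigen, went both ways, 3 of 11 higher and 4 lower, with a median of -0.05, but within 10 of 10 clusters their median was above 0 (0.045 to 1.11).

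The highest ratios in fibroblasts were those of Nr1d1, a repressor of the circadian clock (19.9 and 160 CPM), C1qtnf3 (82.6 and 401 CPM), Ccn3 (110 and 492 CPM) and S100a4 (93.3 and 409 CPM). Crabp2, Myadm, Sema3c, Igfbp5 and Ost4 followed, with log2 ratios of 2.02, 1.74, 1.47, 1.44 and 1.42. At the other end stood the antisense transcript Gt(ROSA)26Sor (227 and 13.6 CPM), Cxcl14 (596 and 85.6 CPM), AY036118 (691 and 102 CPM), Fmo2 (161 and 38.0 CPM), the lipid carrier Apoe (1432 and 352 CPM), Lars2 (300 and 76.4 CPM) and Sdc4 (764 and 215 CPM). By size alone 64 of 3158 genes were at least 2 times higher and 57 at least 2 times lower, and with TMM or median-of-ratios scaling 52 and 68. Clusters 3, 6, 1 and 0 held most conventional fibroblasts and clusters 2, 13 and 8 most No-Touch ones. Several genes named above were among the leading genes of these clusters, so their values depend on the clusters' shares. They were C1qtnf3 in cluster 8, Crabp2 and S100a4 in cluster 13 and Sema3c and Igfbp5 in cluster 2. On the conventional side they were Cxcl14 in cluster 0 and Saa3 and Cxcl13 in cluster 3. Within the 10 fibroblast clusters with 50 cells in both libraries, counting those set aside, the collagen (0.035 to 0.79) and interferon (0.099 to 1.21) medians were above 0 in 10. The cytokine median was above 0 in 5, from -1.42 to 0.48. The complement median was above 0 in 6 (-1.84 to 0.34) and that of matrix glycoproteins in 4 (-0.23 to 0.45). For these 3 lists the class value depends on which clusters each library filled. The size of the collagen difference does too, since its class median lay above that of every cluster. Clusters were made from the same expression without integration, and a change within cells can move them to another cluster. Of the 12 fibroblast clusters 5 came to at least 80% from the conventional and 4 from the No-Touch library. Here and in the classes below, medians within clusters therefore cannot separate cluster makeup from a change within cells.

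Over the whole mural class most inflammatory genes were lower in the No-Touch library and matrix genes were higher, while contractile genes went both ways. Of 24 cytokine and NF-kappaB genes 13 were at least 1.5 times lower and 5 higher (median -0.86, percentile 0). The neutrophil chemokine Cxcl1 was at 5871 CPM (5828 to 5913) and 2300 CPM (2276 to 2325), the chemokine Cxcl5 at 216 and 69.7 CPM, Saa3 at 404 and 91.5 CPM and the cytokine Il11 at 63.8 and 2.79 CPM. The collagenase Mmp13 was at 62.8 and 1.53 CPM. Il11 led a small mural subcluster that came only from the conventional library, and its value without those cells was not computed. Of 20 contractile genes of smooth muscle 5 were higher and 2 lower (median 0.09), with Acta2, smooth muscle actin, at 3837 and 4791 CPM, Lmod1 at 195 and 377 CPM and the filament gene Des at 449 and 234 CPM. Of 23 matrix glycoprotein genes 12 were higher and 1 lower (median 0.60), with Eln, which encodes elastin, at 473 and 1586 CPM and the elastic fibre gene Fbln5 at 87.0 and 408 CPM.

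Sost, an inhibitor of Wnt signalling, was highest by ratio in mural cells (14.5 and 101 CPM; chromosome 11, 101962458 to 101967015), followed by Sfrp2 (155 and 950 CPM), Gxylt2, Gdf10, Fbln5, Ncam1, Nr1d1 and the growth factor Igf1 (35.9 and 152 CPM). Col4a5 and Itgbl1 had log2 ratios of 2.02 and 1.97. A mural subcluster led by the fibroblast genes Dcn, Sfrp2, Fbln1 and Serpinf1, with Igf1, Gxylt2 and Gdf10 among its leading genes, came mostly from the No-Touch library, and over the class Dcn was at 1628 and 3851 CPM. Lowest were Gt(ROSA)26Sor, H2-M9, Marcksl1 (313 and 67.5 CPM), Tnfaip2, Saa3, AY036118, the matrix protease Adamts4 (958 and 266 CPM), Il34, Cxcl5 and Procr. Of 17 genes of TGF-beta signalling 8 were higher and 1 lower (median 0.40), and of 20 interferon genes 6 were higher and 0 lower (median 0.19). Of 5 RNAs kept in the nucleus, Xist among them, 3 were lower and 1 higher (median -0.90, and -0.28 to -0.20 within 3 clusters), with Meg3 at 1592 and 854 CPM and Kcnq1ot1 at 151 and 241 CPM. In all, 153 of 3550 genes were at least 2 times higher and 131 lower, and with median-of-ratios scaling 123 and 161, which moved the median over all genes from 0.02 to -0.09. Cluster 15, with pericyte markers, held 76.4% of conventional and 37.7% of No-Touch mural cells, and cluster 14, with smooth muscle markers, 9.13% and 44.4%. The matrix count was 5 in place of 12 under 4 other settings, and the medians of this list within the 3 mural clusters ran from -0.17 to 0.29. Of these 3 clusters the cytokine median was above 0 in 0 (-0.29 to -0.10), the contractile median in 0 (-0.13 to -0.0064), the TGF-beta median in 0 (-0.29 to -0.20) and the interferon median in 3 (0.42 to 0.88). Within clusters the TGF-beta direction was thus the reverse of that over the class, and the cytokine difference was smaller. The limit given for medians within fibroblast clusters holds here too.

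In blood endothelial cells, genes of capillaries were lower in the No-Touch library and genes of the matrix higher, by less within clusters than over the class. Of 15 capillary and angiogenic genes 10 were at least 1.5 times lower and 0 higher (median -0.89, percentile 0). Gpihbp1, which anchors lipoprotein lipase in capillaries, was at 108 CPM (103 to 114) and 34.4 CPM (30.5 to 38.7), the fatty acid carrier Cd36 at 146 and 52.5 CPM and Angpt2 at 113 and 45.3 CPM. Of 23 matrix genes 12 were higher and 0 lower (median 0.61), with Eln at 129 and 605 CPM and fibronectin, Fn1, at 268 and 1053 CPM. Of 16 genes of the flow response 6 were higher and 0 lower (median 0.44), with the vasoconstrictor Edn1 at 140 and 502 CPM and the transcription factor Klf4 at 524 and 860 CPM.

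Highest by ratio in blood endothelial cells were Cytl1 (12.4 and 279 CPM; chromosome 5, 37735519 to 37739820), Col8a1 (34.7 and 385 CPM), Txndc5, Gxylt2, S100a4, the calcification inhibitor Mgp (688 and 3930 CPM), Col5a2, Ccn1 and Eln. Lowest were Gt(ROSA)26Sor, Akap12, AY036118, Lars2, the interferon-induced Rsad2 (225 and 57.3 CPM), the neutrophil growth factor Csf3 (709 and 184 CPM), Inhbb, the tight junction gene Cldn5 (225 and 71.7 CPM), Gpihbp1 and Tnip1. Rsad2 and Csf3 each led a subcluster that came mostly from the conventional library, and their values without those cells were not computed. Of 20 interferon genes 7 were higher and 2 lower (median 0.48), and of 12 MHC genes 4 were higher and 0 lower (median 0.39), with B2m, the light chain of MHC class I, at 1598 and 3962 CPM. Of 10 leukocyte adhesion genes 1 was higher and 1 lower (median 0.21), with the selectin Selp at 4167 and 5365 CPM and Icam1 at 4196 and 2646 CPM. Of 12 genes of endothelial to mesenchymal transition 7 were higher and 1 lower (median 0.61), but genes of modulated smooth muscle (7 of 12 higher, median 0.72) and contractile genes (4 of 10 higher, 0 lower) went the same way, and fibroblast markers such as Dcn reached up to 11.8% of their fibroblast level in this class. By size 110 of 3552 genes were at least 2 times higher and 70 lower, and with TMM scaling 86 and 93, with median-of-ratios scaling 84 and 96, which moved the median over all genes from -0.02 to -0.12. Cluster 18 held most of this class in both libraries (78.8% and 67.5%), but cluster 23, led by Cytl1 among others, held 1.49% of conventional and 19.1% of No-Touch blood endothelial cells, so genes of that cluster depend on its share. Within the 2 clusters with 50 cells in both libraries the capillary median was -0.44 and -0.23, the matrix median 0.22 in both and the flow median 0.095 and 0.15. The matrix count was 7 with a mitochondrial limit of 5% and 19 with doublets kept, in place of 12.

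In lymphatic endothelial cells, all measured MHC genes and nearly all interferon genes were higher in the No-Touch library. Of 20 interferon response genes 18 were at least 1.5 times higher and 0 lower (median 1.24, percentile 100). The interferon-induced GTPases Irgm1 (24.1 and 126 CPM; chromosome 11, 48861968 to 48871683) and Iigp1 (256 and 988 CPM) and the nucleic acid sensor Zbp1 (46.4 and 222 CPM) were among the highest, with Xaf1 and Gbp3 at log2 ratios of 1.78 and 1.55. Of 11 MHC genes 11 were higher (median 1.75, percentile 100). B2m was at 1423 CPM (1386 to 1460) and 4178 CPM (4111 to 4245; chromosome 2, 122147686 to 122153083), H2-T23 at 185 and 668 CPM and the peptide transporter Tap2 at 49.4 and 168 CPM.

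Lower in No-Touch lymphatic endothelial cells were Gt(ROSA)26Sor, the macrophage growth factor Csf1 (225 and 54.8 CPM), Icam1 (2407 and 595 CPM), Depp1, Gdf15 (934 and 267 CPM), Gadd45b (1772 and 549 CPM), the interferon-induced chemokine Cxcl9 (120 and 42.6 CPM), Creb5, Noct and Neat1. Nfkbia, an inhibitor of NF-kappaB, was at 5049 and 2150 CPM, while the cytokine list as a group had 8 of 21 members lower and 4 higher (median -0.10). Of 14 genes of the unfolded protein response 4 were lower and 0 higher (median -0.48), with the chaperone Hspa5 at 2382 and 1585 CPM. Of 20 immediate early and heat shock genes 8 were higher and 1 lower (median 0.48), with Fos at 1432 and 5542 CPM. Sox18 was at 77.0 and 228 CPM. In total 91 of 3632 genes were at least 2 times higher and 65 lower, with doublets kept 180 and 75, and thinned 123 and 99. Cluster 17 held the whole class in both libraries, and 7 of the 11 MHC genes were left when genes under 10% of their highest class were removed.

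**Figure D2:**
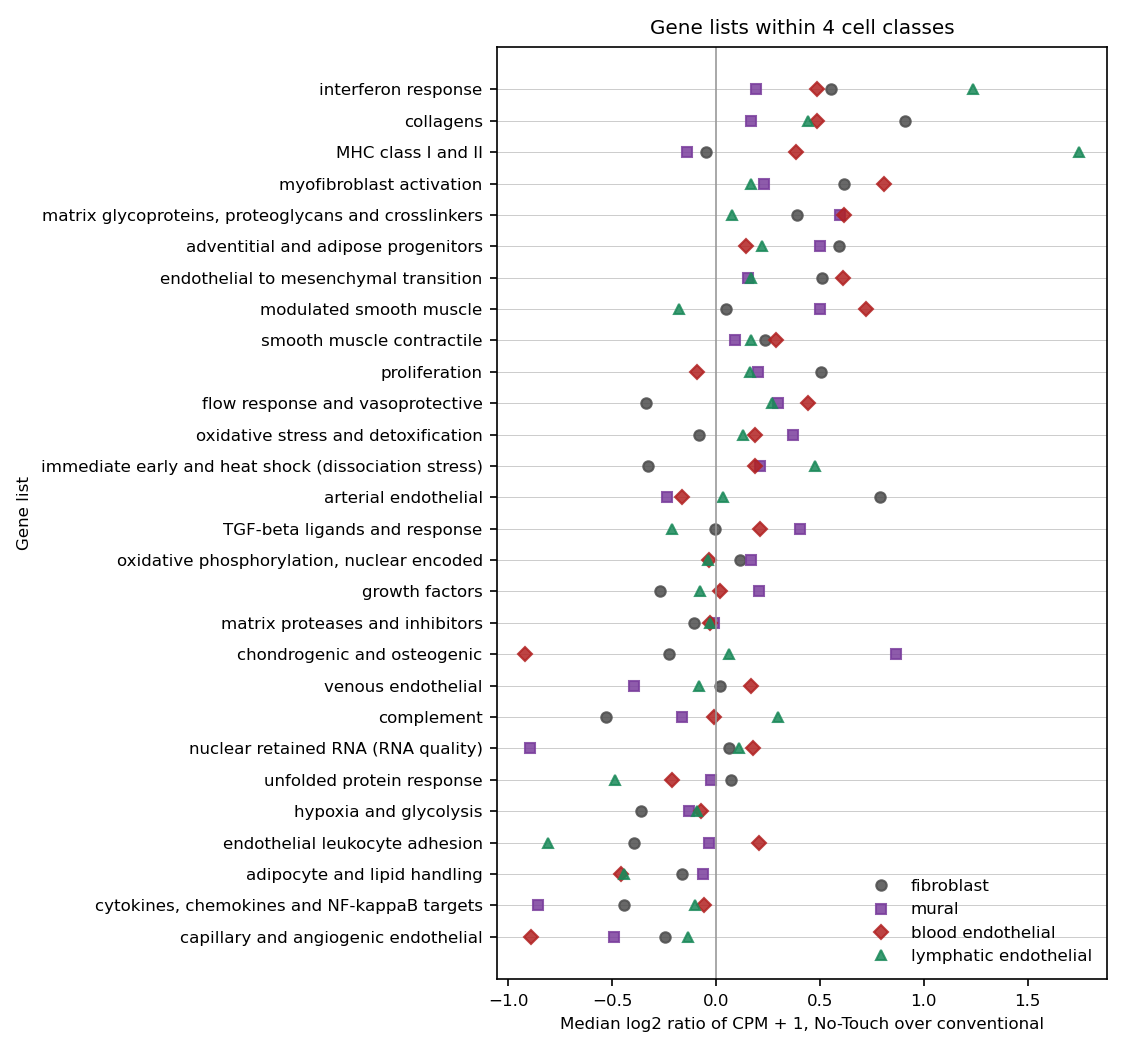
Points give the median log2 ratio of CPM + 1, No-Touch over conventional, of each gene list (vertical axis) in fibroblasts, mural, blood endothelial and lymphatic endothelial cells, with 1 library per group and no error shown. The interferon list lay above 0 in all 4 classes, from 0.19 in mural to 1.24 in lymphatic endothelial cells.

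**Figure D3:**
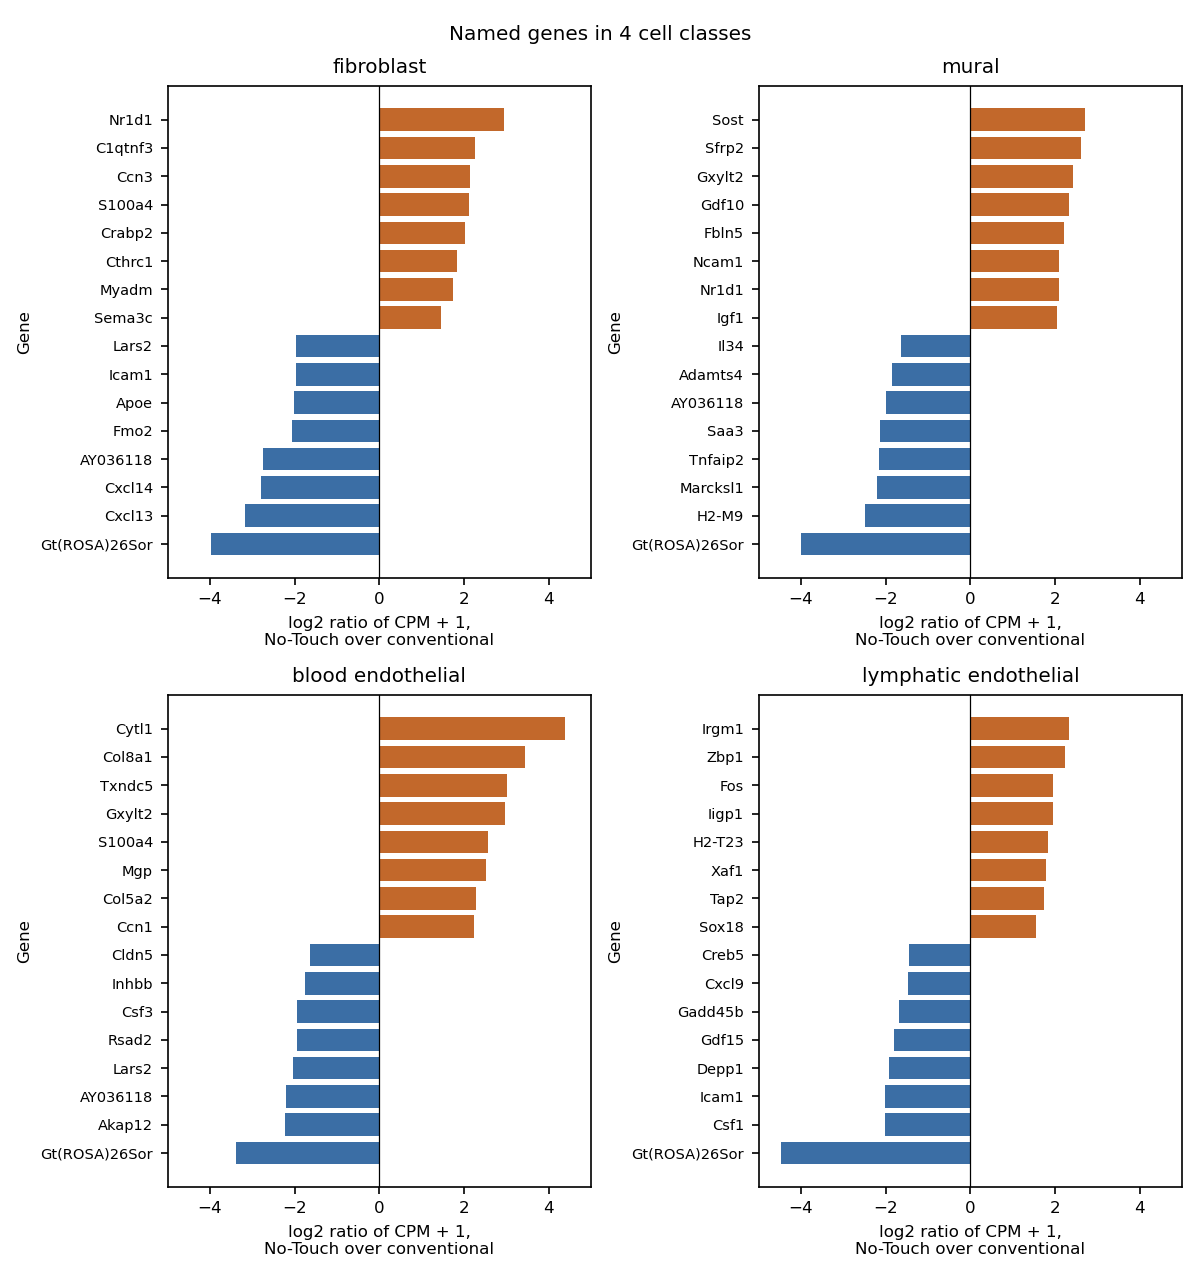
Bars give the log2 ratio of CPM + 1, No-Touch over conventional, of the 8 highest and 8 lowest genes by the fixed rule in each of 4 classes, orange for higher and blue for lower in the No-Touch library. Gt(ROSA)26Sor was lowest in each of them, from -3.38 in blood endothelial to -4.47 in lymphatic endothelial cells.

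The last comparisons concern dividing cells and finer groups. After thinning, Mki67 or Top2a, which mark dividing cells, had a UMI in 1.48% of conventional (84 of 5669) and 2.32% of No-Touch fibroblasts (107 of 4609), a ratio of 1.57 (1.04 to 2.36). With the clusters put back the shares were 1.51% and 1.69%, a ratio of 1.12 (0.773 to 1.62). Neutrophils, which do not divide, had such a UMI in 2.53% (6 of 237) and 1.74% (2 of 115) of cells at the same 3000 UMIs, a background too thin to set a level. With 3 genes of the proliferation list required, fibroblasts were at 4.16% and 5.88% (ratio 1.41, 1.11 to 1.80) and neutrophils at 1.27% and 1.74%. The fibroblast ratio by this rule was 1.24 (1.00 to 1.54) with the clusters put back. Cluster 11, a fibroblast cluster with Top2a and Mki67 among its leading genes, held 57 conventional and 124 No-Touch cells. Shares were 3.72% and 2.37% in blood endothelial, 1.91% and 0.707% in lymphatic endothelial and 1.18% and 0.974% in mural cells. Unthinned, they were 6.12% and 9.11% in fibroblasts, 14.9% and 15.2% in blood endothelial, 5.47% and 4.48% in lymphatic endothelial and 4.52% and 3.52% in mural cells. Mki67 was at 7.28 and 13.5 CPM in fibroblasts, and Top2a at 9.32 and 13.5 CPM.

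Subclusters split largely by library. At least 80% of the cells came from 1 library in 10 of 15 fibroblast, 7 of 8 blood endothelial and 6 of 9 mural subclusters. A subcluster mostly of 1 library can be that library and not a cell state, so shares of subclusters are not compared.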

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

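The tests in this part were chosen only after the results were seen. Xist, the RNA that silences an X chromosome in female cells, had a UMI in 28.3% of conventional cells (27.4 to 29.1) against 0.287% of No-Touch cells, a signal outside the comparisons of the report. Genes of the Y chromosome alone were seen in 5963 conventional cells, Xist alone in 1898 and both in 989. Free Xist RNA would give as many cells with both as independent draws, but their share was 9.68% against 19.2%, a ratio of 0.503, so free RNA alone does not account for it. A conventional library made from animals of both sexes may be the source. Female type shares were taken among cells with Xist alone or Y genes alone. At 3000 UMIs the highest share was 1.39 times the lowest among classes with 100 such cells. It ran from 35.0% (27.7 to 42.8) in lymphatic endothelial cells and 36.1% (34.4 to 37.9) in fibroblasts to 48.7% (44.9 to 52.6) in mural cells. Neutrophils (85 such cells) were at 67.1%. At full depth the shares lay wider apart, at 20.2% (19.1 to 21.3) in fibroblasts and 36.8% (33.6 to 40.0) in mural cells. Schwann cells (126 such cells) were then at 41.3% and neutrophils (209) at 52.6% (45.6 to 59.6), but depth differs between classes. A single mix of tissues and a graft and host of different sex cannot be told apart, since no library of female cells shows how often Xist is detected in each class.

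A cluster led by Pth, the gene of parathyroid hormone, held 1.42% of conventional cells (145) and 7 No-Touch cells, a type not looked for in a vein graft, and is counted in the epithelial-like class of the report. Pth was at 210 CPM in conventional and 13.6 CPM in No-Touch cells with fibroblast scores. Leukocyte classes, which the CD45 sort should remove, still made up 6.69% (6.22 to 7.20) of conventional and 5.06% (4.64 to 5.49) of No-Touch cells.

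The chondrogenic and osteogenic list went in opposite directions in different classes, with a median log2 ratio of 0.86 in mural cells (8 members, 6 higher and 0 lower) and -0.92 in blood endothelial cells (5 members, 2 higher and 3 lower). Within the 3 mural clusters the median was above 0 in 1 (-0.90 to 0.46), and the blood endothelial median was 0.43 with doublets kept, 0.80 with a 4 times higher minimum or without genes under 10% of their highest class, and 0.026 with no minimum. Within 2 blood endothelial clusters it was -0.65 and -0.51. The difference between the classes was not tested.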

How the results depend on the processing

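Equal doublet removal, clusters put back and cells of male type were chosen after seeing the data. Of 377 values of main results under alternatives, 329 stayed within their limits, 46 moved and 2 reversed; of 2204 list medians 251 moved and 9 reversed, and of 10013 values of named genes 3277 moved and 21 reversed. Unless stated, the cause was not tested. No paired analysis was possible because each group is 1 library. Depth limits the smaller classes, and bounds on shares of cycling cells were wide.

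The fibroblast ratio of shares, 0.796, was 0.702 with a mitochondrial limit of 20%, 0.873 with at least 1000 genes and 2000 UMIs, 0.739 with doublets kept, 0.834 and 0.915 at resolution 0.5 and 2.0, and 0.926 with equal doublet removal. It reversed to 1.01 with each library clustered alone and to 1.19 with the clusters put back, by the added cells. The mural ratio, 0.713, was 0.611 with a limit of 5%, 0.628 with the stricter gene and UMI minimum, 0.603 with doublets kept, 0.606 and 0.591 at resolution 0.5 and 2.0, 0.561 thinned and 0.580 with equal doublet removal.

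Counts of genes at least 2 times higher and lower depended on the expression minimum by its construction. With a 4 times higher minimum they were 37 and 25 in blood endothelial cells, 31 and 29 in fibroblasts, 31 and 26 in lymphatic endothelial and 42 and 60 in mural cells. With no minimum they were 557 and 247, 200 and 222, 591 and 407, and 695 and 384. With doublets kept, genes higher were 178 in blood endothelial, 180 in lymphatic endothelial and 96 in mural cells. Mural genes higher were 95 with the 5% limit and 90 at resolution 0.5, and mural genes lower 85 at resolution 2.0 and 202 with separate clustering. Lymphatic endothelial genes lower were 99 thinned. Blood endothelial matrix genes higher were 7 with the 5% limit and 19 with doublets kept. Mural matrix genes higher were 5 with the 5% limit, the stricter minimum, resolution 0.5 and thinning. Without genes under 10% of their highest class 7 MHC genes were higher in lymphatic endothelial cells, by fewer genes. Subclusters mostly of 1 library were 13 in blood endothelial and 10 in mural cells at resolution 1.0.

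In blood endothelial cells the chondrogenic median reversed to 0.43 with doublets kept, 0.80 with the higher minimum and without genes under 10%, and 0.026 with no minimum. Comp was 0.43 with doublets kept, Notch4 0.22 thinned, and Esm1 0.51 thinned and 0.50 with cells weighted equally. The arterial list in fibroblasts (3 members, 0.79) was -0.13 with the stricter minimum, -0.077 at resolution 2.0, -0.040 with separate clustering and -0.12 with clusters put back. In lymphatic endothelial cells Smad7, Lpl and Gpx3 were 0.56, 0.19 and 0.071 with doublets kept, and the adhesion median, -0.81, was 0.28 without genes under 10%. In mural cells Comp, 1.01, was -1.04 with the 5% limit, -0.019 with the stricter minimum, -0.90 with doublets kept, -0.84 at resolution 0.5, -1.55 thinned and -0.53 with equal doublet removal. Ltbp2, 0.70, was -0.67, -0.10, -0.93, -0.77 and -1.19 under the first 5 of these, and Unc5b, 0.69, was -0.023 with the 5% limit, -0.10 with doublets kept and -0.39 thinned.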

Other observations

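The tests on interferon genes and those on genes shared by all classes were chosen only after these patterns were seen. Further lists stood apart in single classes. In fibroblasts 8 of 15 genes of adventitial progenitors were higher and 2 lower in the No-Touch library (median 0.59), with the progenitor marker Cd34 at 219 and 523 CPM, but within 10 clusters the median of the list was above 0 in 6 and ran from -0.43 to 0.39. In blood endothelial cells 5 of 10 lipid handling genes were lower and 3 higher (median -0.46), with Lpl, lipoprotein lipase, at 50.7 and 10.6 CPM and Fabp4 at 2410 and 1492 CPM. Within arterial genes of this class, 2 of 13 were higher and 3 lower (median -0.17), with Bmx at 6.54 and 54.6 CPM and the Notch ligand Dll4 at 141 and 76.6 CPM. In mural cells 6 of 14 genes of modulated smooth muscle were higher and 1 lower (median 0.50; -0.62 to 0.40 within 3 clusters), with Sox9, a transcription factor of cartilage, at 24.6 and 104 CPM.

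Interferon response genes were higher in the No-Touch library in fibroblasts and lymphatic endothelial cells. At 3000 UMIs the list kept at least 102% of its median log2 ratio in both classes. Random thinning barely alters the expected CPM of a class sum, so this cannot decide whether depth per cell plays a part. The value shows only that the ratio did not rest on cell weights or on clustering at unequal depth. Among cells of male type in both libraries the list kept at least 85.0%, which leaves little room for the sex of the cells. Without genes under 10% of their highest class it kept at least 100%, but that filter left 18 of 20 members in both classes. The filter used the higher of the 2 libraries' values, and fibroblast markers reached up to 11.8% of their fibroblast level in endothelial classes. RNA from other cells therefore remains open. A biological difference between the grafts may account for the pattern, as may any other difference between the 2 preparations, and neither was tested.

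Of 2298 genes measured in all 4 classes, 4 were at least 2 times higher and 15 at least 2 times lower in each. Independent classes would give 0.0004 and 0.0001. All classes come from the same 2 libraries, however, so independence could not hold and the overlap is no test. Among these genes were Irgm1, Sfrp2, Has1 and Snhg6 on the higher side. Gt(ROSA)26Sor, AY036118, Lars2, Neat1, Saa3 and Xist were on the lower side. Fibroblast markers reached at most 11.8% of their fibroblast level in the endothelial classes. Of the shared genes, 63.2% lay above that share of their highest class in all 4, Has1 barely so at 12.0% in blood endothelial cells. RNA from other cells at the level of these markers would not by itself reach such values. That level was measured for fibroblast markers only, so it cannot decide whether RNA from other cells set the difference between the libraries. For the other 7, such as Saa3 and Sfrp2, 57.1% lay at or under that level in all classes but 1 or in all. Except for Pth, RNA from other cells cannot be told apart here from expression in the cells themselves. Pth, also among the 7, lay at 0.151% to 0.167% of its highest class in all 4 classes. It had a UMI in 95.4% of conventional and 35.0% of No-Touch cells with fibroblast scores. For Pth these values argue against expression in the cells themselves. Among cells of male type 78.9% stayed 2 times apart, which argues against the sex of the cells for most. In Schwann cells and neutrophils 84.2% kept their direction in both, and a technical difference between the libraries and a biological one that reaches every cell cannot be told apart with 1 library per group.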
